A study of Oncorhynchus masou masou with 2 samples.

How the data were processed

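Total RNA of masu salmon granulosa layers was extracted with a silica column kit and made into mRNA sequencing libraries with an Illumina kit, per the labels' protocols. There were 2 libraries, 1 labelled as having no agent and 1 labelled as incubated with forskolin. The dose, the incubation time and the number of fish or follicles behind each library are not given in the sources used here. The submitters' processing notes name CASAVA and Bowtie, without versions or the role of each, and the assembler, the read filters and the treatment of reads that match several contigs are not given in the sources used here.

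For each library the authors deposited, per contig, its length, a read count and a value in reads per 1000000 counted reads (RPM), per the file headers. The deposited counts were whole numbers. The deposited RPM values equalled the count divided by the sum of all counts in the library, within the rounding of the files to 2 decimals. Both libraries listed the same 97645 contigs in the same order. In both, 9 contigs of 61 to 71 bases had no value, and they were left out, which left 97636 contigs. Counts summed to 4746085 in the control library and 4327458 in the forskolin library. A count of 0 allows up to 3 counts, which is 0.632 RPM in the control library and 0.693 RPM in the forskolin library. The control library had 2870 contigs at 0 and the forskolin library 3431.

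Groups were taken from the agent given in the labels. The 1 comparison of the design, forskolin against control, was made per contig as the log2 ratio of counts over library totals. A pseudocount of 0.5 was added to counts for ranking and for counts of contigs past a fold, and only contigs with at least 20 reads summed over both libraries were used. Contigs at least 2-fold higher or lower were counted. With 1 library per group no test across conditions was made. Intervals of ratios were exact (Clopper-Pearson, conditional binomial) and those of shares of reads exact binomial, all at 95%. Those of single contigs' RPM were exact Poisson intervals. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. The numbers expected from counting error were drawn 100 times by splitting each contig's summed reads in proportion to the library totals.

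The rule for named contigs, for the case that no contig could be given a gene name, was the 2 with the largest log2 rise and the 2 with the largest log2 fall over the minimum of reads. Contig names were compared with the identifiers, symbols and accessions of the masu salmon RefSeq gene table (assembly UVic_Omas_1.1, used for names only), and 0 matched. The 20 gene lists, their medians and their comparison with random lists therefore gave no values. The design and lists, the rule and the first set of alternative settings were fixed before the data were examined. These settings were TMM factors (edgeR), upper-quartile scaling, pseudocounts of 2 and 5 counts, no minimum of reads, a minimum of 100 reads, and 4-fold in place of 2-fold. The 8-fold and 32-fold counts and the alternatives by contig class, length, counts of 0, abundant contigs and other scalings were added after seeing the data.

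The comparison was tested on simulated data, with counts for the 56901 contigs drawn from the pooled shares and the real library totals and 200 contigs changed by a known fold. At a simulated 4-fold change, 93.5% of the changed contigs were past 2-fold in the right direction, and 2.79% of the unchanged contigs were past 2-fold. At a simulated 2-fold change, 47.5% of the changed contigs were past 2-fold. The intervals held the simulated ratio for 96.2% to 96.5% of contigs. The simulated noise was Poisson only, and as many contigs were raised as lowered. The simulation therefore does not show errors from scaling, from unequal directions or from variation beyond counting. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.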

Results

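Messenger RNA of masu salmon ovarian granulosa layers was sequenced in 2 libraries, 1 from layers without an added agent (control) and 1 from layers incubated with forskolin. The granulosa layer is the inner somatic cell layer of the ovarian follicle, and forskolin is a plant diterpene that activates adenylyl cyclase and so raises cyclic AMP, the second messenger of gonadotropins. The series set out to compare mRNA levels between these libraries, in a study of the enzyme that makes the maturation-inducing hormone. The control library held 4746085 counted reads and the forskolin library 4327458, both on the same 97645 contigs (assembled stretches of transcript). There was 1 library per group, so no difference below has a replicate check and no p-value is given. Intervals are exact 95% intervals and cover counting error only.

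Contigs were listed by number, without gene names or sequences, so the values describe contigs and not genes. None of the 97645 contig names matched an entry of the masu salmon gene table. The 20 lists fixed beforehand covered steroid synthesis, hydroxysteroid dehydrogenases, cyclic AMP signalling, ovulation, cell type markers and others. Apart from the ribosomal protein list, which was given by name prefixes, they held 435 gene symbols, and 0 of these could be assigned to a contig. Contig names hold only a class and a number, so no symbol could have matched. The hydroxysteroid dehydrogenase that the study is about was therefore not analysed here. Several contigs can come from 1 transcript, and a count of contigs is not a count of genes. The contigs were short, with a median length of 119 bases and a range of 61 to 5190 bases, and 82.7% of them were under 200 bases.

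The contig names fell into 3 classes. Contigs named as mixed made up 41.0% of the list and took most reads, 81.4% of the control library (95% interval 81.4 to 81.5%) and 81.8% of the forskolin library (81.8 to 81.8%). Contigs named as control singlets took 13.7% of control reads (13.6 to 13.7%) and 8.50% of forskolin reads (8.47 to 8.52%). Contigs named as forskolin singlets took 4.91% of control reads (4.89 to 4.93%) and 9.70% of forskolin reads (9.67 to 9.73%). Over all contigs, 2870 had no control read and 3431 no forskolin read, so most singlets of either class held reads of both libraries. How each class was assembled is not given in the sources used here.

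The forskolin library differed widely from the control library, in both directions. Of the 56901 contigs with at least 20 reads summed over both libraries, 6724 (11.8%) were at least 2-fold higher with forskolin in reads per 1000000 counted reads (RPM), 10137 (17.8%) were at least 2-fold lower, and 40040 (70.4%) lay within 2-fold. The contigs at least 2-fold higher took 4.44% of control reads (4.42 to 4.46%) and 18.6% of forskolin reads (18.6 to 18.7%). Those at least 2-fold lower took 17.2% of control reads (17.1 to 17.2%) and 5.40% of forskolin reads (5.37 to 5.42%). Both sets were picked by their ratio in these same counts, so a gap between the libraries follows from the choice. The intervals of these shares do not cover that choice. Counting error alone, drawn 100 times for libraries with equal shares, put on average 877 contigs at least 2-fold higher and 1040 at least 2-fold lower, and at most 966 and 1105. The exact interval of the ratio lay wholly above 2-fold for 2731 contigs and wholly beyond 2-fold lower for 2472, against at most 5 and 6 in the draws.

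The share of lower contigs among those past 2-fold varied with how the libraries were scaled. With TMM factors in place of library totals, 8806 contigs were at least 2-fold higher and 7609 at least 2-fold lower, so that 46.4% of the contigs past 2-fold were lower against 60.1% with library totals. Upper-quartile scaling gave 7737 higher and 8788 lower, so that 53.2% were lower. TMM factors from mixed contigs alone gave 53.6% lower, and TMM factors from contigs over the minimum 49.9%. TMM factors moved the median log2 ratio of the 56901 contigs from -0.14 to 0.06, a shift of 0.20, and folds below are relative to library totals.

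The largest differences were more often higher than lower with forskolin. At 4-fold the numbers were close, with 2631 contigs higher and 2476 lower. At 8-fold they were 1299 higher and 711 lower, and at 32-fold 407 higher and 139 lower. The singlet classes carried most of these, as 1103 of the 1299 and 391 of the 407 were forskolin singlets, and 620 of the 711 and 131 of the 139 were control singlets. With no pseudocount and only counts of 0 set to 3 counts, 1334 contigs were at least 8-fold higher and 857 lower. At 32-fold 206 were higher and 76 lower. A fold against 0 is not an interval bound in this setting, and nonzero counts under 3 were kept as they were. The setting is therefore not stricter throughout, as its numbers at 8-fold were above those with the pseudocount. In mixed contigs alone, 167 were at least 8-fold higher and 87 lower, and 15 were at least 32-fold higher and 8 lower. Without a minimum of reads the order at 8-fold turned, with 3221 contigs higher and 3529 lower.

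**Figure D1:**
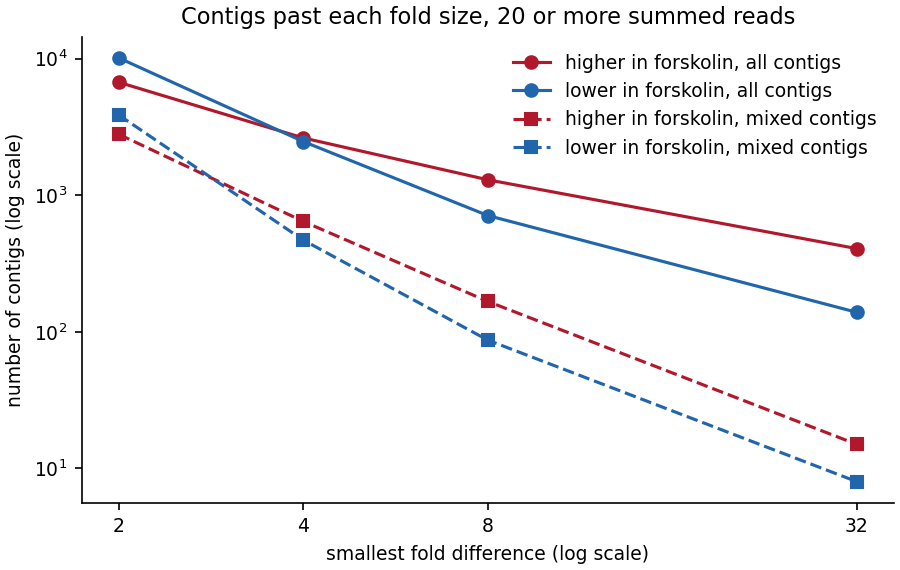
Number of contigs (log scale) at least 2, 4, 8 or 32-fold higher (red) or lower (blue) in the forskolin library than in the control library, for all contigs with 20 or more summed reads (circles, solid lines) and for mixed contigs (squares, dashed lines). With library totals, lower contigs outnumber higher ones at 2-fold (10137 against 6724 for all contigs, an order that TMM factors turn), and higher ones outnumber lower ones at 8-fold (1299 against 711).

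Contigs without a single read in 1 library were more often at 0 in the control library over the minimum of reads, whereas over all contigs more were at 0 in the forskolin library (3431 against 2870). Of the contigs over the minimum, 286 had no control read, and 22 of these had at least 100 forskolin reads. In contrast, 93 had no forskolin read, and 3 of these had at least 100 control reads. Of the 286, 278 were forskolin singlets and 8 were mixed contigs. Of the 93, 91 were control singlets and 2 were mixed contigs.

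The 2 contigs with the highest log2 ratios were both forskolin singlets with no control read. Contig fors-singlet_contig_002206, 464 bases long, had 1189 forskolin reads, or 275 RPM (259 to 291). Set against 3 counts in the control library (0.632 RPM), it was 435-fold higher. This fold and those below are not interval bounds, as they leave out counting error in the other library. The exact upper limit of a 0 was 0.777 RPM in the control library and 0.852 RPM in the forskolin library. Contig fors-singlet_contig_032363, 237 bases long, had 488 forskolin reads, or 113 RPM (103 to 123), and was 178-fold higher on the same basis. The 2 contigs with the lowest log2 ratios were control singlets with no forskolin read. Contig cont-singlet_contig_026816, 152 bases long, had 258 control reads, or 54.4 RPM (47.9 to 61.4). Set against 3 counts in the forskolin library (0.693 RPM), it was 78.4-fold lower. Contig cont-singlet_contig_023694, 248 bases long, had 244 control reads, or 51.4 RPM (45.2 to 58.3), and was 74.2-fold lower on the same basis. Genomic positions and annotations of these contigs were not analysed here.

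Among the 25 contigs with the most summed reads, each with at least 9402, 6 were higher with forskolin by 5.45 to 7.71-fold. These 6 contigs were 536 to 3138 bases long. They lay between 269 and 544 RPM in the control library and between 1864 and 2966 in the forskolin library, and the lowest lower bound of their ratio intervals was 5.23-fold. Together they took 0.214% of control reads (0.210 to 0.218%) and 1.40% of forskolin reads (1.39 to 1.41%). One of the 25, a contig of 136 bases, was lower, at 1451 RPM in the control library and 702 in the forskolin library, a ratio of 0.484 (0.464 to 0.505), which TMM factors moved within 2-fold, to 0.557. The other 18 lay within 2-fold.

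The balance of directions differed between contig classes. Mixed contigs had 2799 at least 2-fold higher and 3874 at least 2-fold lower of 36146 over the minimum. Their median log2 ratio was -0.10, with quartiles of -0.55 and 0.37. TMM factors from all contigs, singlets included, turned the order to 4084 higher and 2542 lower, with a shift of 0.20. TMM factors from mixed contigs alone shifted log2 ratios by only 0.09, and mixed contigs were not counted with them here. The TMM numbers below for mixed contigs also use the factors from all contigs. Control singlets had 308 higher and 6082 lower of 12977, with a median log2 ratio of -0.91. Forskolin singlets had 3617 higher and 181 lower of 7778, with a median log2 ratio of 0.92. At 100 to under 200 summed reads the classes still parted this way. Control singlets there had 29 higher and 190 lower of 413, with a median of -0.73. Forskolin singlets had 202 higher and 20 lower of 388, with a median of 1.08. At 200 to under 500 reads the medians were -0.13 in control singlets and 0.90 in forskolin singlets. At 1000 summed reads or more the classes did not part this way. Control singlets had 9 higher and 6 lower of 56, with a median of 0.32, and forskolin singlets 12 higher and 5 lower of 55, with a median of 0.33. A class named for 1 library is not independent evidence of the direction in that library. Mixed contigs with 20 to under 50 summed reads had 880 at least 2-fold higher and 1156 lower, and those with 200 to under 500 had 408 and 508. Among mixed contigs with 100 to under 200 summed reads, 472 were at least 2-fold higher and 827 lower, and TMM factors turned this order too, to 680 and 556. Among those with 1000 reads or more, 135 were higher and 122 lower, of 1189, and TMM factors gave 163 and 90.

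**Figure D2:**
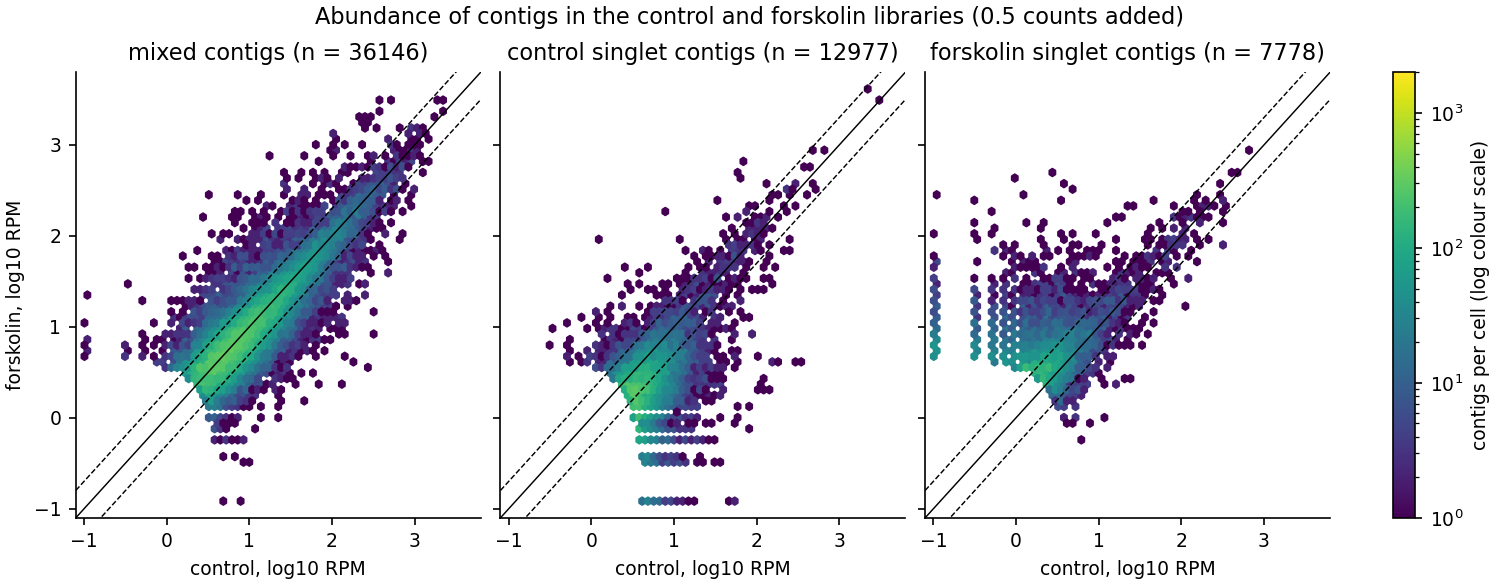
Abundance of each contig with 20 or more summed reads in the control library (x axis) and the forskolin library (y axis), as log10 RPM after adding 0.5 counts, in 3 panels by contig class. Colour gives the number of contigs per cell on a log scale, the solid line marks equal abundance and the dashed lines 2-fold differences. Of the mixed contigs, 81.5% lie within 2-fold, while 46.9% of the control singlets lie at least 2-fold below and 46.5% of the forskolin singlets at least 2-fold above.

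Across contigs over the minimum, which are not independent replicates, log2 abundances in the 2 libraries had a Pearson correlation of 0.70 and a Spearman correlation of 0.65.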

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

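Contigs at least 2-fold higher and lower numbered 6724 and 10137 with library totals, a minimum of 20 summed reads and 0.5 counts added. Of the settings fixed before the data were examined, no minimum of reads gave 16307 higher and 24667 lower, a minimum of 100 reads 1550 and 1933, and 4-fold in place of 2-fold 2631 and 2476. Of the alternatives chosen after seeing the data, mixed contigs alone gave 2799 and 3874, and contigs of 200 bases or more 1605 and 2841. By construction, 4-fold is a stricter size on the same contigs, and fewer or more contigs enter the others. The other 10 settings stayed within 1.5 times, but TMM factors turned the order, with 8806 higher and 7609 lower, and TMM factors from contigs over the minimum gave 8145 and 8123. Upper-quartile scaling gave 7737 and 8788. At 8-fold, 1299 contigs were higher and 711 lower. A pseudocount of 2 gave 418 lower, a pseudocount of 5 gave 520 higher and 167 lower, and no minimum 3221 and 3529, the only setting run in which more were lower. A minimum of 100 reads gave 329 and 158, mixed contigs alone 167 and 87, and contigs of 200 bases or more 375 and 211. The 4 named contigs were picked as extremes with 0 reads in 1 library, so these settings could not turn them and show nothing about their stability. The sums over contigs of 1 gene name and the gene list medians were not run, as no contig had a gene name. No paired analysis was possible because each group had 1 library. At 20 summed reads, counting error alone reaches 2-fold for some contigs, so a single contig's 2-fold difference near the minimum was not detectable at this depth.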

Other observations

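Contigs under 75 bases made up 8.25% of control reads and 9.35% of forskolin reads, and 6 of the 25 contigs with the most summed reads were of this length, all within 2-fold between the libraries. Among contigs over the minimum of reads, 19.4% of those under 75 bases were at least 2-fold higher with forskolin and 11.9% at least 2-fold lower, whereas of contigs of 150 bases or more 9.96% were higher and 18.01% lower. With TMM factors these shares were 24.7% and 9.09% for contigs under 75 bases, and 12.7% and 13.6% for contigs of 150 bases or more. The 25 most abundant contigs of each library took 3.57% of control reads and 5.16% of forskolin reads.

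All patterns below were noticed in these 2 libraries and are hypotheses about them. The tests of mixed contigs alone, of totals without strongly differing contigs, and of intervals past 2-fold were chosen after their results or the pattern had been seen. The bounds for TMM scaling were set before its result was seen, but the explanation was first worded as totals pulled down by strongly raised contigs and was narrowed to scaling afterwards. Intervals of medians come from 2000 resamples of contigs, which are not independent.

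More contigs were at least 2-fold lower than higher with forskolin (60.1% of those past 2-fold). With library totals, the larger number of control singlet than forskolin singlet contigs was not the whole cause, since mixed contigs alone gave 58.1%. With TMM factors from all contigs, however, mixed contigs gave 38.4%, and factors from mixed contigs alone were not used for this share. Scaling by library totals is a candidate explanation, as TMM factors gave 46.4% lower, which met the bound set for it. TMM factors from contigs over the minimum gave 49.9% lower. However, upper-quartile scaling (53.2%) and TMM factors from mixed contigs alone (53.6%) kept a lower majority. Whether strongly raised contigs took reads from the rest stays open, because totals over contigs that differ by less than 4-fold gave 54.5% but leave out contigs by the outcome itself. A larger number of lowered transcripts stays open as a biological explanation that 1 library per group does not test.

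Control singlets had a median log2 ratio of -0.91 and forskolin singlets of 0.92, against -0.10 in mixed contigs. Counting noise in contigs with few reads was weighed as a cause. At 100 to under 200 reads the medians were still -0.73 in control singlets and 1.08 in forskolin singlets, against -0.14 in mixed contigs. The gap was thus not confined to contigs with the fewest reads. Among contigs with 200 or more reads the control singlet median lay only 0.13 from the mixed median, and above it (0.02 to 0.21, 332 contigs against 7124). That difference met the bound set beforehand for counting noise as the cause. The forskolin singlet median lay 0.57 above it (0.46 to 0.73, 304 contigs), but at 500 to under 1000 reads the medians were 0.08 in forskolin singlets and -0.07 in mixed contigs, and at 1000 or more 0.33 in forskolin and 0.32 in control singlets, so the medians of the singlet classes did not part at the highest depth. However, 1469 control singlets had a ratio interval wholly below a 2-fold fall, where draws of counting noise gave at most 6 over all contigs. The draws treat reads as independent molecules, so this later test argues only against that form of noise as the whole cause. A selection on the outcome stays open if each class was built from the library in its name, which the sources used here do not state, and no biological explanation was tested.

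Contigs under 75 bases had a median log2 ratio 0.33 above that of contigs of 150 bases or more (0.32 to 0.40). A different mix of contig classes by length was tested within mixed contigs, where the difference was 0.27 (0.17 to 0.28), so that its lower limit missed the bound of 0.2 set against this explanation but exceeded the 0.1 allowed if class mix were the whole cause. A different read depth was tested in mixed contigs with 200 or more reads, where it was 0.36 (0.22 to 0.47, 194 contigs against 6291), with the lower limit above the bound of 0.2 set against read depth, in a set that also holds the class fixed. Reads that match several short contigs and RNA quality stay open, since the deposited counts do not separate them, and no biological explanation was tested.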
